A study of Mus musculus with 16 samples.

How the data were processed

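RNA was measured in 16 samples of embryonic dorsal root ganglion neurons cultured from CD1 mice, in 4 groups of 4 replicates: DMSO then DMSO, DMSO then nocodazole, DLK inhibitor then DMSO, and DLK inhibitor then nocodazole. Per the labels' protocols, RNA was isolated with a ReliaPrep kit, ribosomal RNA was removed with Kapa RiboErase, and libraries were made from total RNA. The authors deposited 1 table of whole-number counts per Ensembl gene identifier. Per the submitters' processing notes, reads were handled with STAR and Salmon against GRCm39, with no versions given. Which of these made the numbers is not stated, so the whole numbers could be read counts or rounded estimates, and strand settings and the treatment of reads shared between genes are not given. Genes with close paralogs, such as the tubulins, carry that uncertainty.

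The table held 55356 identifiers in 16 columns, and 52080 of them (94.1%) matched a gene symbol in the reference annotation used here, GENCODE M21 on GRCm38. As that build differs from the authors' build, the annotation gave symbols only and no coordinates are reported. Symbols are those of that release. The columns were assigned to groups by their names, which match the labels. Total counts ran from 30987962 to 43321421 per library. No replicate was a copy of another of its group: over the 24 pairs within groups, the chi-square per degree of freedom was 8.28 to 51.3, where counting alone gives 1. CPM, which are counts scaled to a common library size, were computed with the scaled library sizes, and group values are means with the SD of 4 libraries.

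Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Library sizes were scaled by the trimmed mean of M-values, with factors from 0.9595 to 1.064, and genes with too few counts were removed by the default filterByExpr rule, which left 19156 genes (72 without a symbol). A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 16 libraries. It gave 5 contrasts: nocodazole without inhibitor, inhibitor without nocodazole, nocodazole with inhibitor, inhibitor with nocodazole, and the interaction, which is the nocodazole change with inhibitor minus that without. The edgeR adjusted p is the Benjamini-Hochberg value over all tested genes of a contrast, and a gene was called below 0.05. Changes are log2 fold changes with standard errors (SE) derived from the test. Log2 CPM for scores and principal components used a prior count of 2.

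The precision can be read from the median SE over genes, which was 0.144 to 0.145 for the 4 pairwise contrasts and 0.204 for the interaction. The median absolute log2 change among called genes was 0.58, 0.41, 0.56, 0.57 and 0.71 in the order above. The procedure was tested on simulated counts with 18804 genes in the fit. For nocodazole without inhibitor it recovered 82% of 100 genes changed by 1 on the log2 scale and 50% of 100 changed by 0.5, with 7 false calls. For the interaction it recovered 39% of 100 genes at 0.6 and 0% of 100 at 0.3, with 4 false calls. A contrast with no change gave 0 calls, 0 of 40 random lists were called, the 1 changed list was, and a retained share set to 40% came back as 42.6%. Each simulated gene was drawn separately from the others. The simulation therefore could not test the list calls where genes of a list vary together. In the data the estimated correlation between the tubulin genes was 0.904.

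Gene lists, 29 in number with 811 genes, were written before the data were examined, as were the comparisons, the naming rule and the alternatives, except those named in the closing section as added later. The lists were regeneration-associated genes, ATF4 and integrated stress response genes, endoplasmic reticulum unfolded protein response genes, tubulin genes, microtubule-associated protein genes, tubulin-modifying enzyme genes, kinesin and dynein transport motor genes, neurofilament genes, actin cytoskeleton and SRF target genes, DLK and JNK pathway genes, dual-specificity phosphatase genes, AP-1 and ATF transcription factor genes, activity and immediate early genes, p53 target and cell death genes, sensory neuron identity genes, voltage-gated ion channel genes, synaptic vesicle and release genes, axon guidance genes, NRF2 and heat shock genes, cholesterol synthesis genes, interferon response genes, proliferation and mitosis genes, Schwann cell and satellite glia markers, fibroblast markers, endothelial markers, macrophage markers, pericyte and smooth muscle markers, mitochondrially encoded genes and pan-neuronal genes. Some genes stand in several lists. Each list was tested with camera from limma at its preset correlation between genes of 0.01, and camera adjusted p is the Benjamini-Hochberg value over 145 tests (29 lists in 5 contrasts). Beside it stands the adjusted p with the correlation estimated from the data. With that estimate no list was called in any contrast, the lowest adjusted p being 0.128, so camera calls of lists hold only for the preset correlation. Counts of called list members are given over all genes and again with p-values adjusted over the list alone.

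Named genes followed a fixed rule. For nocodazole without inhibitor and for the interaction these were the 10 largest increases and 10 largest decreases, and for the other contrasts the 5 largest of each. They were taken among called genes with a mean log2 CPM of at least 1 and, for pairwise contrasts, no overlap between the libraries of the groups, passing over symbols without a gene name. Up to 4 members of each list with the smallest p, and a fixed set (Atf3, Jun, Ddit3, Atf4, Sox11, Gap43, Sprr1a, Gal, Stmn2, Tubb3, Tuba1a, Tubb5, Map3k12, Map3k13, Bbc3 and Mki67, with 1 more that is not reported here), were added. Sprr1a had 5 counts over all libraries and was not tested.

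The retained share is the mean nocodazole response with inhibitor as a percentage of that without, over called genes turned to a positive response. To keep selection apart from measurement, genes were selected in 2 DMSO and 2 nocodazole libraries and both responses measured in the other libraries, for 6 choices. The correlation expected from shared DMSO libraries was taken from simulated groups without effects.

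The alternatives were other scaling (DESeq2 size factors, or none), no filter or a stricter one (CPM of at least 1), the DESeq2 1.42.0 Wald test, limma-voom, an adjusted p under 0.01, an absolute log2 change of at least 1, the replicate number as a block, fitting only the compared groups, camera with estimated correlation, fry, and leaving out each library. Added later were the sample number in the labels as a covariate, 2 surrogate variables from sva 3.50.0, and leaving out 2 libraries together. Sequence reads, alignments and isoforms were not analysed here.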

Results

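Transcripts were counted in cultures of embryonic dorsal root ganglion neurons from CD1 mice, the sensory neurons whose axons carry touch, temperature and pain signals. The neurons had grown for 6 days in vitro with nerve growth factor, and with fluorodeoxyuridine and uridine, which hold back dividing cells. Each culture then received DMSO or a 500 nM dose of GNE3511, an inhibitor of dual leucine zipper kinase (DLK, the product of Map3k12), which signals axon damage through the JNK pathway to the nucleus. After 15 min, DMSO or 200 nM nocodazole was added for 16 h. Nocodazole binds free tubulin and makes microtubules disassemble. The design asks how neurons respond to loss of microtubules and how much of that response needs DLK. As a single compound at a single dose was used, effects through DLK cannot be told apart from effects on other targets. There were 4 groups of 4 samples, called here DMSO, nocodazole, inhibitor, and inhibitor plus nocodazole. Total RNA was sequenced after removal of ribosomal RNA, and each library held between 30987962 and 43321421 counts. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

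The first principal component of expression held 38.2% of the variance and separated the nocodazole group from the rest. Its 4 libraries scored between 59.5 and 69.7, the DMSO libraries between -26.5 and -12.2, and the inhibitor libraries between -41.6 and -9.7. In the inhibitor plus nocodazole group, replicates 2 to 4 scored between -31.4 and -28.4, beside the groups without nocodazole, and replicate 1 scored 10.4. Transcripts of the mitochondrial genome, a rough sign of RNA or cell quality, made up between 0.765% and 1.78% of the counts, with 1.71% in that replicate 1. Malat1, a nuclear long noncoding RNA, lay between 11220 and 12780 CPM (counts scaled to the library size) in the nocodazole group and between 6161 and 8398 CPM in the DMSO group. It lay between 8796 and 11570 CPM in the inhibitor group and between 8957 and 11370 CPM in the inhibitor plus nocodazole group.

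**Figure D1:**
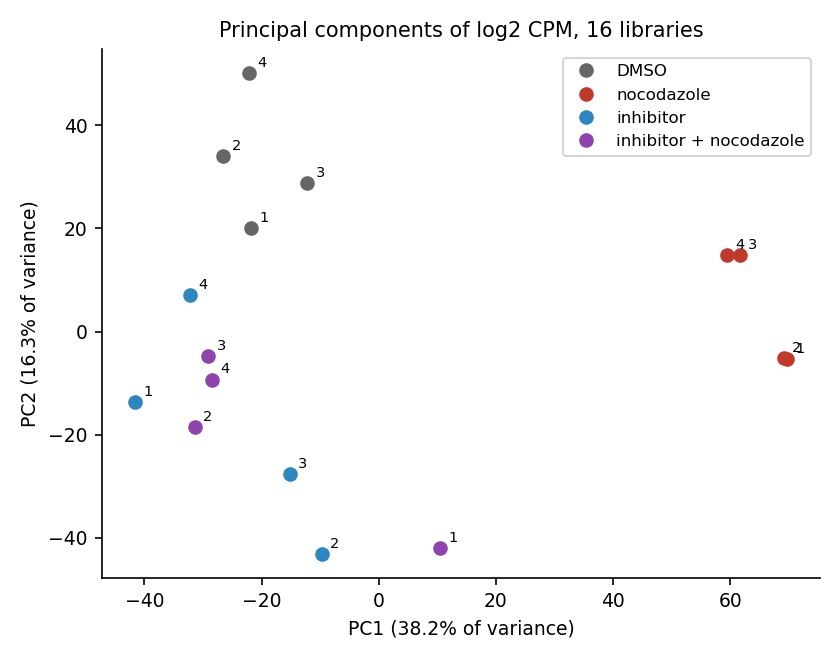
Scores of the 16 libraries on the first (x axis, 38.2% of variance) and second (y axis, 16.3% of variance) principal components of log2 CPM; each point is 1 library, coloured by group, with its replicate number. The nocodazole libraries lie between 59.5 and 69.7 on the first component, and inhibitor plus nocodazole replicate 1 lies at 10.4, apart from the other replicates of its group.

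The first comparison asked what nocodazole did without the inhibitor. The injury-induced transcription factor gene Atf3 and all 43 measured integrated stress response genes were higher after nocodazole, and all 11 measured tubulin genes were lower. Atf3 (ENSMUSG00000026628), a transcription factor switched on in sensory neurons after axon injury, went from 4.25 ± 3.11 CPM (SD, n = 4) in DMSO to 181 ± 25.5 CPM (SD, n = 4), a log2 change of 5.38 ± 0.385 (SE, edgeR adjusted p = 4.96e-08). Tubb3, the neuronal β-tubulin, went from 3070 ± 202 CPM to 1010 ± 203 CPM (SD, n = 4). The log2 change was -1.60 ± 0.186 (edgeR adjusted p = 6.47e-06). Of the 19156 genes tested, 3556 rose and 3631 fell, which is 37.5% in all, and 1231 and 702 of them moved by at least 2-fold.

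In the list of AP-1 and ATF transcription factor genes, 10 of 14 measured members rose and none fell (11 and 0 adjusted over the list alone). Their median log2 change was 1.68 (camera adjusted p = 9.35e-07, but adjusted p = 0.128 with an estimated correlation). Its members included Fosl2, a Fos-family partner of Jun, at 3.21 ± 0.179 (edgeR adjusted p = 4.77e-09), and Mafk, a small Maf protein, at 1.70 ± 0.15 (edgeR adjusted p = 3.95e-07). Jun itself, the main nuclear target of JNK, rose from 70.3 ± 27.1 to 223 ± 50.2 CPM, a log2 change of 1.66 ± 0.576 (edgeR adjusted p = 0.0316). That call for Jun was lost without DMSO replicate 1 (edgeR adjusted p = 0.0895) or 2 (0.0809), and without nocodazole replicate 3 (0.0727) or 4 (0.0541), and in DESeq2 (adjusted p = 0.0737). Of 29 regeneration-associated genes, 14 rose and 6 fell (15 and 9 adjusted over the list alone). The list median was 0.42 (camera adjusted p = 0.0236, adjusted p = 0.208 with an estimated correlation). Among them were Sox11, a transcription factor of axon growth, at 1.58 ± 0.149 (edgeR adjusted p = 8.29e-07), and Tnfrsf12a, a receptor of the TNF family, at 3.56 ± 0.25 (edgeR adjusted p = 4.38e-08). The injury markers Gap43, Gal and Stmn2 did not pass the test, with log2 changes of -0.25, 0.34 and -0.17. Activity and immediate early genes rose in 10 of 15 cases and fell in 1 (10 and 2 adjusted over the list alone). Their median was 1.56 (camera adjusted p = 0.000105, adjusted p = 0.146 with an estimated correlation), led by Egr1 at 5.56 ± 0.305. Dusp1 and Dusp16, phosphatases that switch MAP kinases off, rose by 3.03 and 1.47 on the log2 scale. Over the 13 dual-specificity phosphatase genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), and the list as a whole did not pass (median 0.35, camera adjusted p = 0.0526).

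All 43 measured ATF4 and integrated stress response genes rose (43 adjusted over the list alone). The median log2 change was 0.82 (camera adjusted p = 5.63e-23, adjusted p = 0.208 with an estimated correlation). Ddit3, which encodes the stress transcription factor CHOP, went from 29.6 ± 6.94 to 198 ± 40.7 CPM (SD, n = 4). The log2 change was 2.73 ± 0.282 (edgeR adjusted p = 1.87e-06). Sesn2, a stress-induced regulator of growth signalling, rose by 1.98, and Atf4 itself by 0.68. Of 24 endoplasmic reticulum unfolded protein response genes, 9 rose and 5 fell (11 and 6 adjusted over the list alone), and the list did not pass (median 0.12, camera adjusted p = 0.102). Its chaperones Dnajb9 and Hspa5 rose by 1.74 ± 0.077 and 1.21 ± 0.089 on the log2 scale. In the list of p53 target and cell death genes, 20 of 32 rose and 2 fell (20 and 2 adjusted over the list alone). Their median log2 change was 0.44 (camera adjusted p = 3.65e-05, adjusted p = 0.128 with an estimated correlation). Bbc3, which encodes the death-promoting protein PUMA, went from 38.1 ± 10.2 to 147 ± 24.2 CPM (SD, n = 4). The log2 change was 1.95 ± 0.177 (edgeR adjusted p = 5.32e-07), and Mdm2, the ubiquitin ligase that acts on p53, rose by 1.37 ± 0.071. NRF2 and heat shock genes rose in 8 and fell in 4 of 28 cases (8 and 4 adjusted over the list alone) with no call for the list (median 0.05, camera adjusted p = 0.231), although the haem-degrading enzyme gene Hmox1 rose by 2.72 ± 0.201 (edgeR adjusted p = 6.88e-08).

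**Figure D2:**
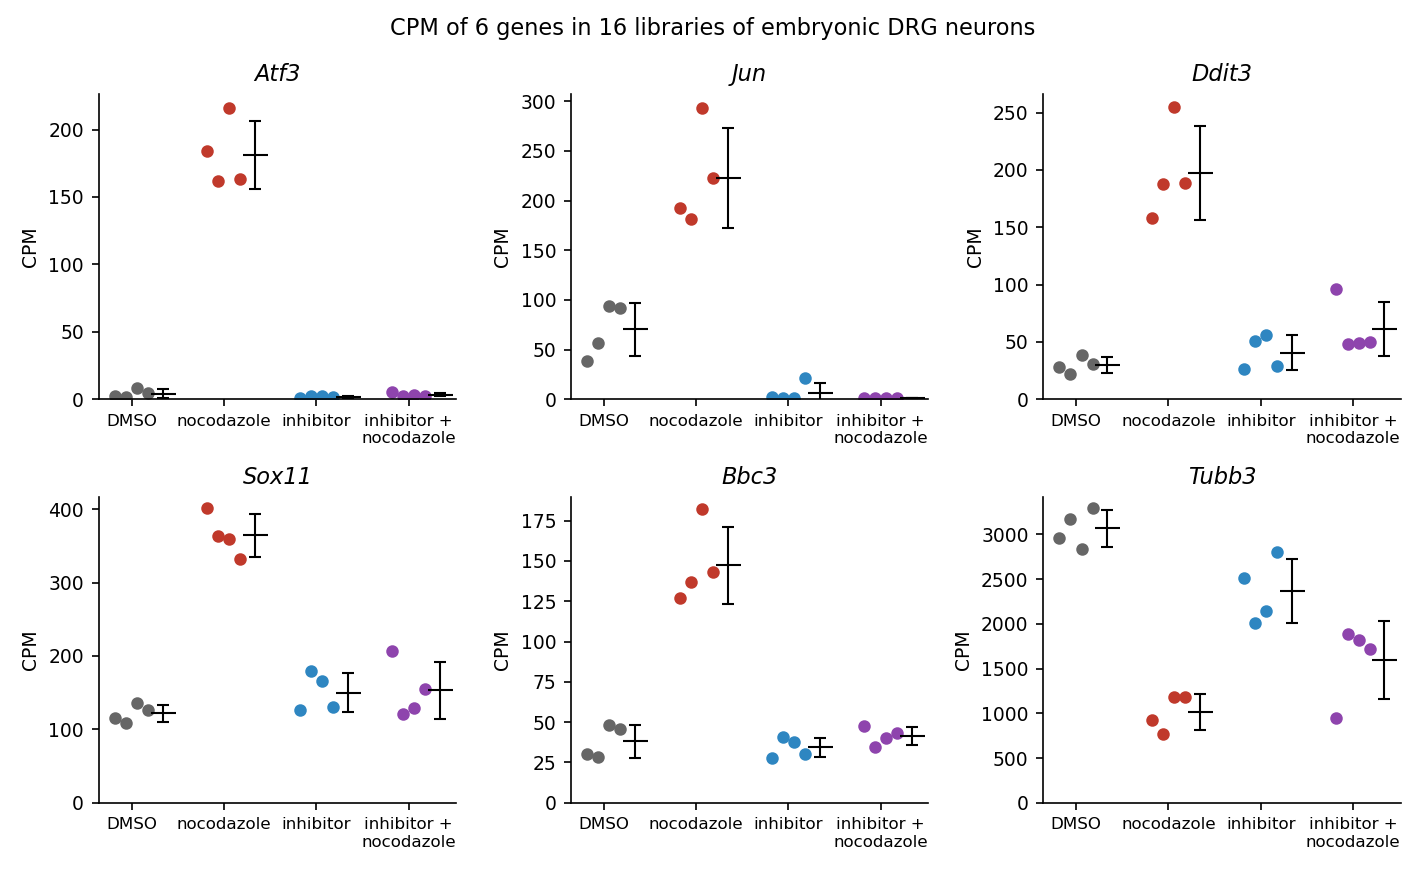
CPM (y axes, linear and starting at 0) of Atf3, Jun, Ddit3, Sox11, Bbc3 and Tubb3 in the 4 groups; points are the 4 libraries of a group, and the dash and bar give their mean ± SD. Atf3 averages 181 CPM with nocodazole alone and 3.51 CPM with inhibitor plus nocodazole, while Tubb3 averages 1010 and 1590 CPM.

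All 11 measured tubulin genes fell (11 adjusted over the list alone). The list median was -1.17 (camera adjusted p = 2.69e-08, adjusted p = 0.296 with an estimated correlation). Tuba1b fell from 1460 ± 101 to 531 ± 60.3 CPM (SD, n = 4). The log2 change was -1.45 ± 0.138 (edgeR adjusted p = 8.9e-07), and Tuba1a and Tubb5 had log2 changes of -1.21 and -1.07. Tubulin genes are near copies of each other, so the value of each single gene is uncertain, since reads could have been divided among them. Of 55 microtubule-associated protein genes, 7 rose and 21 fell (7 and 24 adjusted over the list alone). Their median was -0.16 (camera adjusted p = 0.00272, adjusted p = 0.477 with an estimated correlation). Mtus2 and Nav2 were among those that fell, at -1.07 and -1.13. The tubulin-modifying enzyme genes (5 up, 6 down of 27, and 5 and 6 adjusted over the list alone, camera adjusted p = 0.948), the kinesin and dynein transport motor genes (4 up, 10 down of 42, and 4 and 9 adjusted over the list alone, camera adjusted p = 0.206) and the neurofilament genes (1 of 5 down, and 1 adjusted over the list alone, camera adjusted p = 0.31) did not pass as lists. Within them, Vash2, part of an enzyme that removes the last tyrosine of α-tubulin, rose by 0.93, and Kif26b fell by 1.37 on the log2 scale. Among actin cytoskeleton and SRF target genes, 11 of 36 rose and 1 fell (11 and 1 adjusted over the list alone). Their median of -0.04 and mean of 0.60 differed in sign, and the list did not pass (camera adjusted p = 0.16). Map3k12, the gene of DLK, fell by 0.35 ± 0.065 on the log2 scale (edgeR adjusted p = 0.000474). Over 27 DLK and JNK pathway genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone) with no call for the list (camera adjusted p = 0.338).

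Of 47 voltage-gated ion channel genes, 4 rose and 35 fell (4 and 37 adjusted over the list alone). The median log2 change was -0.49 (camera adjusted p = 5.65e-09, adjusted p = 0.237 with an estimated correlation). Kcna2, a potassium channel that limits firing, went from 96.7 ± 9.11 to 48.2 ± 8.94 CPM (SD, n = 4, edgeR adjusted p = 5.2e-06). Sensory neuron identity genes fell in 16 and rose in 4 of 33 cases (17 and 4 adjusted over the list alone). Their median log2 change was -0.45 (camera adjusted p = 0.00551, adjusted p = 0.237 with an estimated correlation). Prdm12, a transcription factor of pain-sensing neurons, fell from 771 ± 30.9 to 450 ± 68.2 CPM (SD, n = 4). Axon guidance genes rose in 9 and fell in 23 of 47 cases (10 and 24 adjusted over the list alone, median -0.40, camera adjusted p = 0.00517, adjusted p = 0.487 with an estimated correlation), with Flrt2 at -2.43 ± 0.11 and Sema6a at 1.96 ± 0.152. Synaptic vesicle and release genes rose in 2 and fell in 15 of 41 cases (2 and 17 adjusted over the list alone, median -0.16, camera adjusted p = 0.00381, adjusted p = 0.536 with an estimated correlation). Of 22 pan-neuronal genes, 3 rose and 7 fell (3 and 7 adjusted over the list alone), with a median of -0.15 at the edge of the threshold (camera adjusted p = 0.0495, adjusted p = 0.536 with an estimated correlation). That list's call was lost without DMSO replicate 4 (camera adjusted p = 0.0732), nocodazole replicate 1 (0.0754) or nocodazole replicate 2 (0.088). Elavl4, a neuronal RNA-binding protein gene of that list, had a log2 change of -1.31 ± 0.147. The largest decrease under the fixed naming rule was that of Adamts15, a matrix protease, from 25.4 ± 2.88 to 1.39 ± 0.954 CPM (SD, n = 4), followed by Grhl3, Palmd and Oprk1. Under the same rule, which passes over weakly expressed genes such as Egr1, the largest increases after Atf3 were those of Dusp4, at 4.04 ± 0.7, and Arid5a, at 3.84 ± 0.413.

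The second comparison asked what the inhibitor did without nocodazole. The inhibitor lowered Jun, Jund and 8 of 13 genes for phosphatases that act on MAP kinases. It also lowered 12 of 36 actin cytoskeleton and SRF target genes, and raised 12 of 43 integrated stress response genes. Jun went from 70.3 ± 27.1 CPM to 6.36 ± 9.87 CPM (SD, n = 4). The log2 change was -3.43 ± 0.65 (edgeR adjusted p = 0.00319). Its level was 21.1 CPM in inhibitor replicate 4, and without that library the log2 change was -5.61 (edgeR adjusted p = 3.31e-07). Jund, a more constantly expressed Jun-family gene, went from 281 ± 46.5 to 70.1 ± 32.5 CPM (SD, n = 4, edgeR adjusted p = 0.000126). In all 1107 genes rose and 1387 fell, and 222 and 147 of them moved by at least 2-fold.

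Of 13 dual-specificity phosphatase genes, 8 fell and none rose (8 and 1 adjusted over the list alone). The list median was -0.50 (camera adjusted p = 4.12e-06, adjusted p = 0.128 with an estimated correlation). Dusp8, a phosphatase that prefers JNK and p38, went from 171 ± 23.9 to 75.6 ± 12.7 CPM (SD, n = 4). The log2 change was -1.18 ± 0.107 (edgeR adjusted p = 3.3e-05). Dusp1 and Dusp16 had log2 changes of -2.81 ± 0.343 and -1.98 ± 0.229. Actin cytoskeleton and SRF target genes fell in 12 of 36 cases and rose in none (13 and 2 adjusted over the list alone). Their median was -0.20 (camera adjusted p = 3.85e-06, adjusted p = 0.208 with an estimated correlation). Zyx, a focal adhesion protein gene, went from 64.5 ± 12.2 to 27.0 ± 4.65 CPM (SD, n = 4), and Tpm4, a tropomyosin gene, had a log2 change of -0.83. Fibroblast markers, of which none of 15 was called over all genes or adjusted over the list alone, had a median of -0.31 in this comparison (camera adjusted p = 0.0977). Of the 29 regeneration-associated genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone, median -0.17, camera adjusted p = 0.00535, adjusted p = 0.128 with an estimated correlation). Stmn4, a microtubule-destabilising protein gene, fell by 2.11 on the log2 scale, and Gap43, a growth cone protein gene, by 0.48, a call lost with the sample number in the model (edgeR adjusted p = 0.0547). The AP-1 and ATF list did not pass (1 up, 4 down of 14, 2 and 5 adjusted over the list alone, camera adjusted p = 0.113). Activity and immediate early genes fell in 5 of 15 cases (5 adjusted over the list alone, median -0.63, camera adjusted p = 0.0192, adjusted p = 0.344 with an estimated correlation), a call lost without inhibitor replicate 1 (camera adjusted p = 0.0711).

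ATF4 and integrated stress response genes rose in 12 of 43 cases and fell in none (20 and 0 adjusted over the list alone). The median log2 change was 0.30 (camera adjusted p = 3.3e-08, adjusted p = 0.477 with an estimated correlation), or 0.20 without DMSO replicate 2. The list score was 0.55 and 0.52 in inhibitor replicates 2 and 3, whose mitochondrial shares were the highest of their group (1.387% and 1.78%). It was 0.10 in each of replicates 1 and 4, within the DMSO range of -0.24 to 0.17. Gpt2, an aminotransferase gene, rose by 0.45 ± 0.052 (edgeR adjusted p = 0.000126). Synaptic vesicle and release genes fell in 9 of 41 cases (13 down and 2 up adjusted over the list alone, median -0.11, camera adjusted p = 0.000522, adjusted p = 0.477 with an estimated correlation), with a median of -0.18 without DMSO replicate 1 and -0.21 without inhibitor replicate 1. Slc17a6, a vesicular glutamate transporter gene, went from 421 ± 8.86 to 288 ± 22.7 CPM (SD, n = 4). NRF2 and heat shock genes rose in 2 and fell in 8 of 28 cases (3 and 11 adjusted over the list alone, median -0.20, camera adjusted p = 0.00742, adjusted p = 0.237 with an estimated correlation). Kinesin and dynein transport motor genes rose in 2 and fell in 10 of 42 cases (5 and 12 adjusted over the list alone, median -0.07, camera adjusted p = 0.0203, adjusted p = 0.536 with an estimated correlation), and this call was lost without inhibitor replicate 2 (camera adjusted p = 0.0705). The nociceptor sodium channel gene Scn10a, of the sensory neuron list, had a log2 change of -0.37 ± 0.061 (edgeR adjusted p = 0.00105).

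Among tubulin genes none passed the edgeR test over all genes or adjusted over the list alone, and the list median was -0.24 (camera adjusted p = 0.0303, adjusted p = 0.657 with an estimated correlation). The tubulin call was lost without DMSO replicate 4 (camera adjusted p = 0.0596), inhibitor replicate 2 (0.0844) or inhibitor replicate 3 (0.0523). Mitochondrially encoded genes had a median of 0.46 (camera adjusted p = 0.000695, adjusted p = 0.544 with an estimated correlation) with no single gene called over all genes or adjusted over the list alone, and a median of 0.27 without inhibitor replicate 3, whose mitochondrial share was 1.78%. Schwann cell and satellite glia markers, which also include Gap43, fell in 5 of 17 cases (6 adjusted over the list alone, median -0.09, camera adjusted p = 0.0324, adjusted p = 0.237 with an estimated correlation). The glial call was lost without DMSO replicate 1, 2 or 3, nocodazole replicate 1 or 4, inhibitor replicate 1, 3 or 4, or any replicate of inhibitor plus nocodazole (camera adjusted p between 0.0522 and 0.0964). Map3k12 had a log2 change of -0.02 (edgeR adjusted p = 0.843). The DLK and JNK pathway list did not pass (3 up, 5 down of 27, 4 and 9 adjusted over the list alone, camera adjusted p = 0.128), though Tnik, a kinase gene upstream of JNK, rose by 0.48 ± 0.062.

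The number of higher genes in this comparison depended on single libraries. It was 588, 730 or 518 without DMSO replicate 2, 3 or 4, and 643, 490 or 515 without inhibitor replicate 1, 2 or 3, while the number of lower genes was 756 without DMSO replicate 4, 752 without inhibitor replicate 2 and 775 without inhibitor replicate 3. Without scaling of library composition the balance turned to 1308 higher and 1065 lower, and with the sample number in the model 366 and 596 genes were called.

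The third comparison asked what nocodazole did in the presence of the inhibitor. Very few single genes passed the test: 15 rose and 1 fell. Atf3 was at 1.84 ± 0.641 CPM (SD, n = 4) with inhibitor and at 3.51 ± 1.41 CPM (SD, n = 4) with inhibitor plus nocodazole, and the difference did not pass (log2 change 0.97 ± 0.438, edgeR adjusted p = 0.827). The unadjusted p was under 0.05 for 1146 genes, and DESeq2 called 118 higher and 7 lower, limma-voom 16 and 1.

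Erg28, which encodes a scaffold of the sterol synthesis enzymes, rose from 22.8 ± 1.01 to 44.5 ± 3.56 CPM (SD, n = 4), a log2 change of 0.96 ± 0.124 (edgeR adjusted p = 0.00644), against 0.67 without inhibitor. Per3, a circadian clock gene, rose from 8.07 ± 0.561 to 14.8 ± 1.52 CPM (SD, n = 4), a log2 change of 0.87 ± 0.116 (edgeR adjusted p = 0.00644), against 0.68 without inhibitor. Lpin1, a lipid phosphatase gene, rose by 0.89 ± 0.124 (edgeR adjusted p = 0.00725) and Usp1, a deubiquitinase gene of DNA repair, by 1.47 ± 0.203 (edgeR adjusted p = 0.00725). The calls of Lpin1 and Usp1 were lost without inhibitor replicate 3 (edgeR adjusted p = 0.0537 for each), and that of Usp1 also when only the compared groups were fitted (0.104) or with the sample number in the model (0.0638). Usp1 had a log2 change of 0.36 without inhibitor. The gene that fell, Rusc1, had a log2 change of -0.33 ± 0.058 (edgeR adjusted p = 0.0456). Its call was lost without DMSO replicate 2 or 3, nocodazole replicate 1, 2 or 4, any inhibitor replicate, or inhibitor plus nocodazole replicate 2, 3 or 4 (edgeR adjusted p between 0.0511 and 0.208).

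None of the 25 measured cholesterol synthesis genes passed edgeR over all genes, and all 25 were higher when adjusted over the list alone, with a median log2 change of 0.49 (camera adjusted p = 1.52e-34, adjusted p = 0.128 with an estimated correlation). Cyp51, a demethylase of the pathway, was at 184 ± 26.5 CPM with inhibitor and 298 ± 50.5 CPM (SD, n = 4) with nocodazole added, and Mvd was at 127 ± 27.0 and 232 ± 47.8 CPM. The mean score of the cholesterol list, relative to DMSO, was 0.15 in inhibitor plus nocodazole replicate 1 and between 0.63 and 0.73 in replicates 2 to 4. Among ATF4 and integrated stress response genes 15 of 43 were higher adjusted over the list alone, none over all genes, with a median of 0.26 (camera adjusted p = 4.92e-27, adjusted p = 0.175 with an estimated correlation), or 0.17 without inhibitor plus nocodazole replicate 1. Tubulin genes had a median of -0.32 (4 of 11 lower adjusted over the list alone, none over all genes, camera adjusted p = 6.8e-09, adjusted p = 0.28 with an estimated correlation), or -0.16 without that library, in which Tubb3 was at 945 CPM against 1720 to 1880 CPM in the others of its group. AP-1 and ATF genes had a median of 0.13 (3 up and 1 down adjusted over the list alone, none over all genes, camera adjusted p = 0.00803, adjusted p = 0.353 with an estimated correlation). The AP-1 median was 0.05 and not called without that same library (camera adjusted p = 0.262), and 0.27 without inhibitor replicate 2.

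Smaller shifts passed camera for p53 target and cell death genes (median 0.13, none called singly or adjusted over the list alone, camera adjusted p = 6.52e-06, adjusted p = 0.128 with an estimated correlation), and for endoplasmic reticulum unfolded protein response genes (1 up, 2 adjusted over the list alone, median 0.07, camera adjusted p = 6.55e-05, adjusted p = 0.175 with an estimated correlation). They also passed for NRF2 and heat shock genes (none called singly or adjusted over the list alone, median 0.08, camera adjusted p = 0.000252, adjusted p = 0.128 with an estimated correlation). The unfolded protein response median was 0.05 without inhibitor plus nocodazole replicate 3, and the NRF2 median 0.13 without inhibitor replicate 4. Mitochondrially encoded genes had a median of -0.20 (none called singly or adjusted over the list alone, camera adjusted p = 0.000183, adjusted p = 0.536 with an estimated correlation). Their call was lost without inhibitor replicate 3 (median -0.08, camera adjusted p = 0.0558) or inhibitor plus nocodazole replicate 4 (-0.10, 0.135), and the median was -0.33 without inhibitor plus nocodazole replicate 1. Regeneration-associated genes had a median of 0.05, with no member called over all genes, and were not called (camera adjusted p = 0.619).

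Without inhibitor plus nocodazole replicate 1, 83 genes rose and 5 fell. Higher genes numbered 10 without nocodazole replicate 2 or 4, 9 without nocodazole replicate 1, 7 without DMSO replicate 1, 2 or 3, 8 without DMSO replicate 4, 5, 8, 3 and 6 without inhibitor replicates 1 to 4, and 5, 6 and 6 without inhibitor plus nocodazole replicates 2 to 4; lower genes numbered 2 without nocodazole replicate 3.

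**Figure D3:**
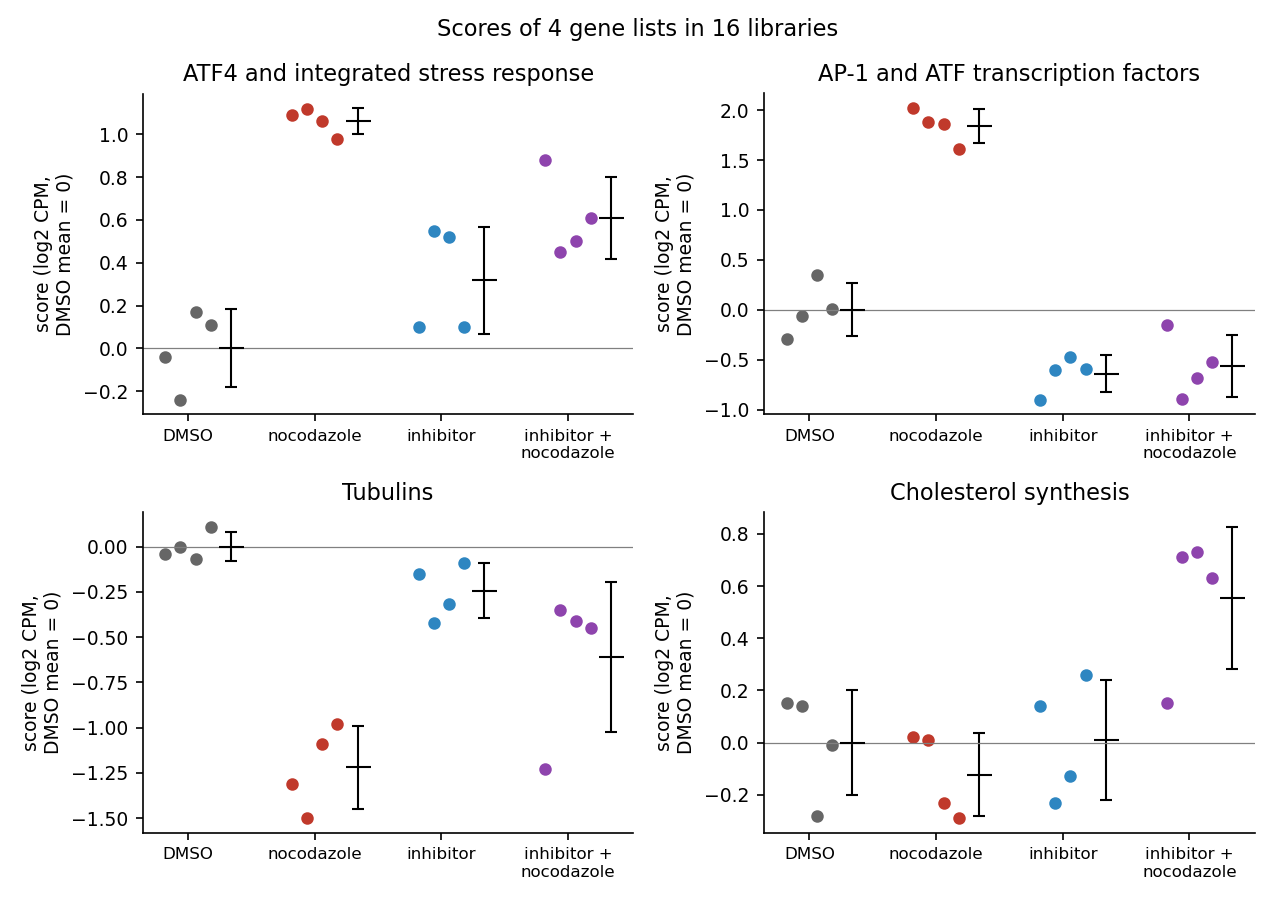
Mean log2 CPM of the genes in 4 lists (y axes, DMSO mean set to 0) for the 4 groups; points are libraries, and the dash and bar give the mean ± SD of the 4 libraries. The tubulin score of inhibitor plus nocodazole replicate 1 is -1.23, against -0.45 to -0.35 in the other replicates of its group, and the nocodazole libraries lie between -1.50 and -0.98.

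The fourth comparison asked what the inhibitor did in the presence of nocodazole. With the inhibitor added, the transcription factor genes Jun and Atf3 were far lower than with nocodazole alone. In contrast, 9 of 11 tubulin genes, 22 of 47 ion channel genes and 20 of 25 cholesterol synthesis genes were higher. Jun was at 223 ± 50.2 CPM (SD, n = 4) with nocodazole alone and 1.26 ± 0.283 CPM (SD, n = 4) with inhibitor as well, a log2 change of -7.48 ± 0.817 (edgeR adjusted p = 3.35e-06). Atf3 had a log2 change of -5.67 ± 0.393 (edgeR adjusted p = 3.22e-08) and Dusp1 one of -5.99 ± 0.358 (edgeR adjusted p = 6.92e-09). In all 3396 genes rose and 3098 fell, 753 and 956 of them by at least 2-fold.

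AP-1 and ATF genes fell in 10 of 14 cases and rose in 2 (10 and 2 adjusted over the list alone). Their median log2 change was -2.24 (camera adjusted p = 3.85e-06, adjusted p = 0.128 with an estimated correlation). Activity and immediate early genes fell in 10 of 15 cases and rose in 1 (11 and 1 adjusted over the list alone, median -1.16, camera adjusted p = 1.75e-05, adjusted p = 0.128 with an estimated correlation). Vgf, a neuropeptide precursor gene, was at 834 ± 177 CPM with nocodazole alone and at 126 ± 85.7 CPM (SD, n = 4) with the inhibitor. Dual-specificity phosphatase genes fell in 9 of 13 cases and rose in 2 (9 and 2 adjusted over the list alone, median -1.66, camera adjusted p = 0.000107, adjusted p = 0.186 with an estimated correlation). Regeneration-associated genes fell in 14 and rose in 4 of 29 cases (15 and 5 adjusted over the list alone, median -0.46, camera adjusted p = 0.000481, adjusted p = 0.128 with an estimated correlation), with Sox11 at -1.25 ± 0.148 and Stat3, a cytokine-responsive transcription factor gene, at -1.01 ± 0.081. Actin cytoskeleton and SRF target genes fell in 15 and rose in 3 of 36 cases (17 and 3 adjusted over the list alone, median -0.14, camera adjusted p = 8.4e-05, adjusted p = 0.278 with an estimated correlation), with a median of -0.24 without nocodazole replicate 2. Fibroblast markers fell in 6 and rose in 1 of 15 cases (7 and 1 adjusted over the list alone, median -0.86, camera adjusted p = 0.0495, adjusted p = 0.491 with an estimated correlation). Dcn, a matrix proteoglycan gene among them, had a log2 change of -2.28 (edgeR adjusted p = 0.000811). The fibroblast call was lost without DMSO replicate 1 (camera adjusted p = 0.0595) or 4 (0.0526), nocodazole replicate 3 (0.0717) or 4 (0.0912), inhibitor replicate 3 (0.0523), or inhibitor plus nocodazole replicate 1 (0.125) or 3 (0.0667).

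ATF4 and integrated stress response genes fell in 21 and rose in 2 of 43 cases (23 and 2 adjusted over the list alone). The list median was -0.31 (camera adjusted p = 8.69e-06, adjusted p = 0.536 with an estimated correlation). Ddit3 fell by 1.70 on the log2 scale, while Atf4 was at 377 ± 47.5 and 378 ± 27.5 CPM (SD, n = 4). p53 target and cell death genes fell in 13 and rose in 3 of 32 cases (13 and 4 adjusted over the list alone, median -0.28, camera adjusted p = 0.00551, adjusted p = 0.266 with an estimated correlation), with Bbc3 at -1.83 ± 0.176. NRF2 and heat shock genes fell in 8 of 28 cases (8 adjusted over the list alone, median -0.10, camera adjusted p = 0.0212, adjusted p = 0.28 with an estimated correlation), a call lost without inhibitor plus nocodazole replicate 1 (camera adjusted p = 0.057). Tubulin genes rose in 9 of 11 cases (10 adjusted over the list alone, median 0.65, camera adjusted p = 0.000292, adjusted p = 0.529 with an estimated correlation), with Tubb5 at 0.67 ± 0.12 (edgeR adjusted p = 0.000393). Voltage-gated ion channel genes rose in 22 and fell in 4 of 47 cases (22 and 4 adjusted over the list alone, median 0.21, camera adjusted p = 8.28e-05, adjusted p = 0.477 with an estimated correlation). Cholesterol synthesis genes rose in 20 and fell in 1 of 25 cases (22 and 1 adjusted over the list alone, median 0.68, camera adjusted p = 5.54e-08, adjusted p = 0.477 with an estimated correlation). Stard4, a sterol carrier gene, was at 80.7 ± 29.2 CPM with nocodazole alone and at 224 ± 38.6 CPM (SD, n = 4) with the inhibitor. Sensory neuron identity genes (11 up, 6 down of 33, 12 and 6 adjusted over the list alone) and axon guidance genes (19 up, 8 down of 47, 20 and 8 adjusted over the list alone) did not pass as lists (camera adjusted p = 0.139 and 0.0975). Flrt2, a guidance receptor gene, rose by 2.90 ± 0.111 (edgeR adjusted p = 4.73e-11).

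The interaction tests directly whether the nocodazole response differed with the inhibitor. For the injury transcription factor genes Atf3 and Sox11 and the death gene Bbc3 the nocodazole increase was smaller with the inhibitor. For 9 of 11 tubulin genes and 20 of 47 ion channel genes the interaction was positive. The interaction was negative for Atf3 (log2 -4.41 ± 0.58, edgeR adjusted p = 0.000116), Egr1 (-6.13 ± 0.7, edgeR adjusted p = 3.47e-05), Sox11 (-1.55 ± 0.208, edgeR adjusted p = 0.000129) and Bbc3 (-1.67 ± 0.245, edgeR adjusted p = 0.000282). It was positive for Adamts15 (3.97 ± 0.569, edgeR adjusted p = 0.000232) and for Flrt2 (2.35 ± 0.146, edgeR adjusted p = 1.81e-07). In all it was positive for 1824 genes and negative for 1763. Of the genes called for nocodazole without inhibitor, 1711 of 3556 higher and 1745 of 3631 lower ones had a called interaction opposing that change (48.1% each). For the other 1845 and 1886 no interaction was called, which does not show that their response was kept. Both tests use the same DMSO and nocodazole libraries, which favours opposing interactions among these genes.

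To measure what was left of the response, genes were selected in 2 DMSO and 2 nocodazole libraries and measured in the other libraries. The mean response with inhibitor was 9.47% of that without it, as the median of 6 such choices, with a range of 6.33% to 10.9%. Across all 19156 genes, which are not independent replicates, the nocodazole changes with and without inhibitor had a Pearson correlation of 0.17 (Spearman 0.16) and the same sign in 54.9%. Among the 7187 genes called without inhibitor the correlation was 0.32 and the sign matched in 64.4%. Without inhibitor plus nocodazole replicate 1, the retained share was -1.26% and the correlation over all genes -0.08. The retained share was also 3.38%, 15.5% and 5.10% without inhibitor replicate 1, 2 and 4.

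**Figure D4:**
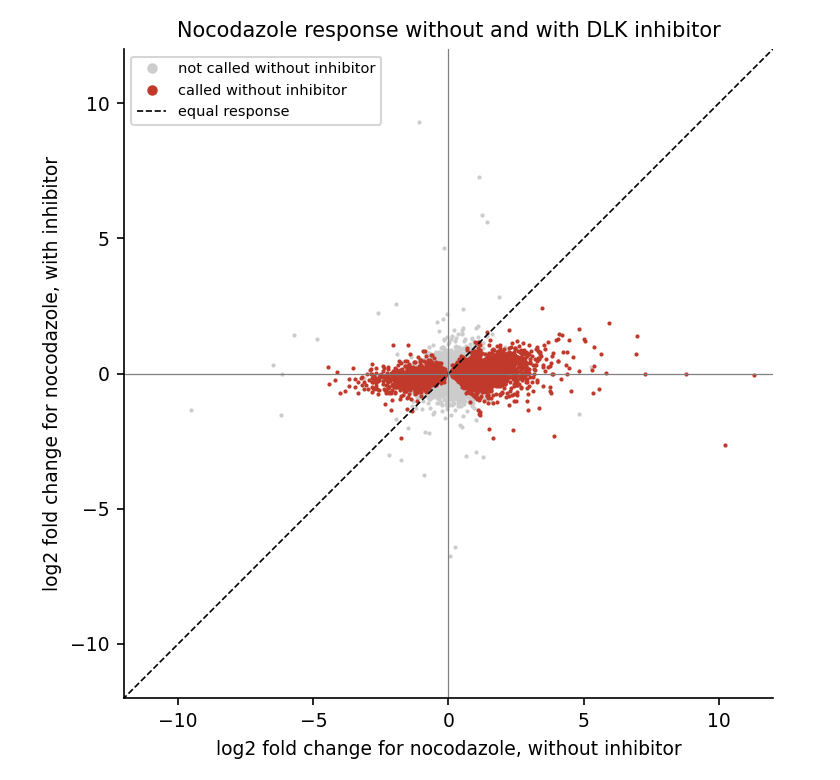
Log2 change with nocodazole without inhibitor (x axis) against that with inhibitor (y axis) for the 19156 genes tested; each point is 1 gene, red for the 7187 called without inhibitor and grey for the others, and the dashed line marks equal responses. Most of the spread lies along the x axis, and the correlation is 0.17 over all genes and 0.32 over those called.

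By list, the interaction was negative in 29 of 43 ATF4 and integrated stress response genes and positive in none (33 and 0 adjusted over the list alone). Their median was -0.61 (camera adjusted p = 3.65e-15, adjusted p = 0.28 with an estimated correlation). Ddit3 had an interaction of -2.15 ± 0.381 (edgeR adjusted p = 0.00121), and that of Atf4 did not pass (-0.27 ± 0.128, edgeR adjusted p = 0.152). AP-1 and ATF genes were negative in 8 of 14 cases (9 adjusted over the list alone, median -1.71, camera adjusted p = 3.2e-05, adjusted p = 0.174 with an estimated correlation). Fosl2 stood at -2.67 ± 0.248 (edgeR adjusted p = 7.64e-06), and Jun at -4.05 ± 0.998 (edgeR adjusted p = 0.0105), a call not made by limma-voom (adjusted p = 0.0579). Without inhibitor replicate 4, the library with the highest Jun of its group, the interaction of Jun was -1.87 (edgeR adjusted p = 0.0205). Activity and immediate early genes were negative in 9 and positive in 1 of 15 cases (9 and 1 adjusted over the list alone, median -1.47, camera adjusted p = 0.0039, adjusted p = 0.237 with an estimated correlation). p53 target and cell death genes were negative in 10 and positive in 2 of 32 cases (13 and 2 adjusted over the list alone, median -0.34, camera adjusted p = 0.00176, adjusted p = 0.235 with an estimated correlation). Regeneration-associated genes were negative in 8 and positive in 3 of 29 cases (10 and 4 adjusted over the list alone, median -0.31, camera adjusted p = 0.0471, adjusted p = 0.237 with an estimated correlation). The regeneration call was lost without DMSO replicate 3 (camera adjusted p = 0.0526), nocodazole replicate 3 (0.0504) or 4 (0.0542), inhibitor replicate 4 (0.092), and inhibitor plus nocodazole replicate 1 (0.121, median -0.68) or 2 (0.053), and its median was -0.49 without inhibitor replicate 1. For actin cytoskeleton and SRF target genes the median of 0.06 and mean of -0.61 differed in sign, 9 of 36 were negative (11 adjusted over the list alone), and the list was not called (camera adjusted p = 0.266).

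Tubulin genes had a positive interaction in 9 of 11 cases (11 adjusted over the list alone). The median log2 change was 0.85 (camera adjusted p = 4.12e-06, adjusted p = 0.447 with an estimated correlation). Tubb3 stood at 1.03 ± 0.258 (edgeR adjusted p = 0.0117), a call lost with the sample number in the model (edgeR adjusted p = 0.0844), and Tuba1b at 1.06 ± 0.192 (edgeR adjusted p = 0.00146). Microtubule-associated protein genes were positive in 12 and negative in 5 of 55 cases (16 and 5 adjusted over the list alone, median 0.20, camera adjusted p = 0.00174, adjusted p = 0.466 with an estimated correlation). Voltage-gated ion channel genes were positive in 20 and negative in 2 of 47 cases (25 and 3 adjusted over the list alone, median 0.43, camera adjusted p = 9.98e-08, adjusted p = 0.28 with an estimated correlation), and sensory neuron identity genes positive in 8 of 33 (8 adjusted over the list alone, median 0.42, camera adjusted p = 0.00535, adjusted p = 0.237 with an estimated correlation). Axon guidance genes were positive in 14 and negative in 3 of 47 cases (18 and 7 adjusted over the list alone, median 0.35, camera adjusted p = 0.00434, adjusted p = 0.483 with an estimated correlation). Synaptic vesicle and release genes were positive in 6 and negative in 1 of 41 cases (6 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 0.0061, adjusted p = 0.536 with an estimated correlation). Pan-neuronal genes were positive in 5 and negative in 1 of 22 cases (6 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.022, adjusted p = 0.508 with an estimated correlation), with a median of 0.28 without nocodazole replicate 3. Cholesterol synthesis genes were positive in 15 of 25 cases (24 adjusted over the list alone, median 0.67, camera adjusted p = 5.54e-08, adjusted p = 0.477 with an estimated correlation). Mitochondrially encoded genes had a median of -0.46 with no single gene called over all genes (camera adjusted p = 0.0105, adjusted p = 0.64 with an estimated correlation), a call lost without nocodazole replicate 2 (camera adjusted p = 0.0527) or inhibitor plus nocodazole replicate 4 (0.07).

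With the sample number in the model the interaction was called for 884 genes in the positive and 917 in the negative direction. Without inhibitor plus nocodazole replicate 1 the numbers were 2740 and 2478.

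The nocodazole and inhibitor effects, each measured against the same DMSO libraries, had a Pearson correlation of 0.28 across genes (Spearman 0.33). Unchanged groups simulated against shared controls gave 0.48, and splitting the DMSO libraries between the comparisons gave 0.16 (range 0.05 to 0.22). The simulated groups hold no effects, so the shared libraries make up more of their variance. The simulated 0.48 can therefore not be set directly against 0.28. The observed covariance was 0.0759, against 0.03 simulated.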

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

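The tests of both sample swaps, of a single wrong label, of uneven exposure or a sample from outside the groups, of the spread within the inhibitor groups, and of inhibitor plus nocodazole replicate 1 as the whole cause were chosen only after the results were seen. Single libraries were compared with the other 3 of their group in 188 sets of values, and 18 sets held a library far from the others, where chance gives about 1 in 20, or 9.4 sets.

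Of those 18 sets, 11 concerned inhibitor plus nocodazole replicate 1. Its list scores (mean log2 CPM relative to DMSO) were -1.23 for tubulin genes (others of its group -0.45 to -0.35), -0.17 for microtubule-associated protein genes (-0.08 to -0.07), -0.10 for transport motor genes (0 to 0.01), -0.30 for synaptic vesicle genes (-0.13 to -0.12) and -0.38 for axon guidance genes (-0.05 to -0.03). Its CPM were 0.841 for Jun (1.38 to 1.44), 96.3 for Ddit3 (48.5 to 49.8), 1200 for Stmn2 (1770 to 1820), 945 for Tubb3 (1720 to 1880), 2830 for Tuba1a (5150 to 5710) and 1700 for Tubb5 (2500 to 2600). In inhibitor replicate 2 the motor score was -0.08 (0 to 0.01), and in inhibitor replicate 1 Map3k12 was at 127 CPM (118 in the others). Nocodazole replicate 4 scored 1.19 for activity and immediate early genes (1.61 to 1.64) and 0.38 for proliferation genes (0.14 to 0.18). Nocodazole replicate 1 had 1.887% of its counts in the most counted identifier (2.662% to 2.787%), DMSO replicate 3 scored 0.35 for pericyte markers (-0.14 to -0.11), and DMSO replicate 4 scored 0.05 for pan-neuronal genes (-0.02 to -0.01).

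The first pattern weighed was the low tubulin mRNA in inhibitor plus nocodazole replicate 1. A swap with an inhibitor library is argued against by the cholesterol score. The lowest of the other inhibitor plus nocodazole replicates lay 0.37 above the highest inhibitor library, so by this score no inhibitor library was out of place. However, replicate 1 itself scored 0.15, within the -0.23 to 0.26 of the inhibitor libraries. A swap with, or a wrong label on, a nocodazole library is argued against by Atf3, which lay 6.9 SD below the nocodazole mean in this library, and a wrong label on a DMSO or inhibitor library by the tubulin score itself, which lay 0.81 below the lowest of those 8 libraries (SD 0.15 in the inhibitor group). RNA quality as the whole cause is argued against by the mitochondrial share, since the tubulin score lay at -3.17 standard errors from the -0.74 that share and group predicted, although that prediction is itself below the other replicates of the group. What stays open is uneven exposure to nocodazole or a sample from outside the groups: with a score of -1.23 these cannot be told apart, as the labels give 1 dose for the group, and no biological explanation was tested, since the design names none for a single replicate.

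The second pattern was the small number of genes called for nocodazole with inhibitor, 16 against 7187 without it. Larger spread within the inhibitor groups as the sole reason is argued against by the small size of the response. Its retained share was at most 10.9% over the 6 choices of DMSO and nocodazole libraries. All libraries with inhibitor entered each choice, and leaving out 1 library at a time gave -1.26% to 15.5%. Inhibitor plus nocodazole replicate 1 contributed, since 88 genes were called without it. It was not the whole cause, since those were 1.13% of the number called without inhibitor when that library was left out. A dependence of the response on DLK, which the design names, may account for the rest and stays a hypothesis examined only on these data. With a single compound, an effect on another target cannot be told apart from it. Weaker exposure of inhibitor plus nocodazole replicates 2 to 4 to nocodazole cannot be told apart from it either. Their tubulin scores were -0.45 to -0.35, against -0.42 to -0.09 in the inhibitor libraries. Their cholesterol scores, however, lay at least 0.37 above those of the inhibitor libraries.

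The third pattern was the 7187 genes called for nocodazole without inhibitor while DMSO libraries carry mostly high sample numbers (2, 16, 18 and 20, against 6, 8, 10 and 12). With the sample number as a covariate, 84.2% of these calls were kept in the same direction. This argues against a straight drift along that number as their cause. For the inhibitor with nocodazole 90.8% were kept. For the inhibitor without nocodazole, nocodazole with inhibitor and the interaction 37.9%, 25% and 47.4% were kept, so a drift is not argued against there. Libraries with inhibitor carry only odd numbers (1 to 13, and 7 to 19 with nocodazole) and the others only even ones. A linear covariate cannot tell that arrangement from the inhibitor itself.

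The nocodazole response differed between cultures with and without inhibitor, by the interaction test, for 1824 genes in the positive and 1763 in the negative direction. By list, the median interaction was -0.31 for regeneration-associated genes, -0.61 for integrated stress response genes, 0.85 for tubulin genes, 0.20 for microtubule-associated protein genes, -1.71 for AP-1 and ATF genes, -1.47 for activity and immediate early genes, -0.34 for p53 target genes, 0.42 for sensory neuron identity genes, 0.43 for ion channel genes, 0.17 for synaptic vesicle genes, 0.35 for axon guidance genes, 0.67 for cholesterol synthesis genes, -0.46 for mitochondrially encoded genes and 0.18 for pan-neuronal genes. None of these lists was called with an estimated correlation.

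Other splits of the same libraries were counted, the real split included. For nocodazole without inhibitor 1 of 35 splits gave 7187 genes or more (highest other 0). For the inhibitor without nocodazole 1 of 35 gave 2494 or more (highest other 1). For the inhibitor with nocodazole 1 of 35 gave 6494 or more (highest other 1802). The real split thus gave the most genes in each of these contrasts. But 1 of 35 is the lowest share possible, and the other splits mix the groups, which widens the spread within them. Chance is therefore not fully excluded for these counts. For the interaction all 16 libraries were regrouped, which also breaks up the nocodazole and inhibitor effects. These splits therefore cannot decide whether chance accounts for the interaction count. Of 80 drawn splits 1 gave 3587 or more, and the highest other gave 3519. That split set nocodazole replicates 2 to 4 and inhibitor plus nocodazole replicate 1 together, so it points to a structure of the samples, as does the split with 1802 genes, and the next gave 1641. For nocodazole with inhibitor 2 of 35 splits gave 16 or more, so chance is not excluded; the highest other, 61 genes, set inhibitor replicates 1 to 3 beside inhibitor plus nocodazole replicate 1 and also points to a structure of the samples. For the number of lists, adjusted within each contrast, chance is not excluded in any contrast: 3 of 35 splits gave 13 or more (highest other 15), 8 of 35 gave 11 or more (highest other 16), 17 of 35 gave 8 or more (highest other 13), 7 of 35 gave 12 or more (highest other 16), and 4 of 80 gave 14 or more (highest other 15), in the order of the report.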

How the results depend on the processing

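The fits with the sample number as a covariate, with 2 surrogate variables, and omitting inhibitor plus nocodazole replicate 1 and inhibitor replicate 4 together were chosen after the results were seen. No named gene and no list turned its direction past the threshold in any alternative. Where a count below changed, the cause was not tested, except that stricter thresholds call fewer genes by construction. Pairs below are genes higher and lower.

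For nocodazole with inhibitor (15 and 1) the counts were 30 and 0 without scaling, 28 and 0 without a filter, 118 and 7 with DESeq2, 5 and 0 with the replicate number as a block, 6 and 0 with only the compared groups, 4 and 0 with the sample number, 91 and 35 with surrogate variables, 103 and 7 omitting both libraries, and 2 genes were lower with the stricter filter. For the inhibitor without nocodazole (1107 and 1387) they were 366 and 596 with the sample number and 642 and 872 with surrogate variables, and 646 genes were higher without a filter and 1817 omitting both libraries. For the interaction (1824 and 1763) they were 884 and 917 with the sample number and 3015 and 2722 omitting both libraries.

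At an adjusted p under 0.01 the counts, in the order of the report, were 2349 and 2361, 315 and 581, 5 and 0, 2253 and 2054, and 790 and 753. With an absolute log2 change of at least 1 they were 1231 and 702, 222 and 147, 1 and 0, 753 and 956, and 387 and 854. Camera with an estimated correlation called 0 lists in each contrast, against 12, 11, 8, 12 and 14 with the preset one. Fry called 19 lists for nocodazole without inhibitor, 5 with inhibitor, and 22 for the inhibitor with nocodazole, and camera without a filter called 19 for the inhibitor without nocodazole.

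Leaving out 1 library gave, for nocodazole without inhibitor, 3053 to 3793 genes higher and 3100 to 3977 lower; for the inhibitor without nocodazole 490 to 1448 and 752 to 1739; for nocodazole with inhibitor 3 to 83 and 0 to 5; for the inhibitor with nocodazole 2777 to 3751 and 2577 to 3467; and for the interaction 1328 to 2740 and 1266 to 2478. The lists called were 12 to 15, 9 to 12, 8 to 10, 11 to 13 and 13 to 14. The retained share ran from -1.26% to 15.5% and the correlation of the nocodazole changes from -0.076 to 0.302, and each was negative only without inhibitor plus nocodazole replicate 1. The other alternatives gave a retained share of 9.04% to 10.5% and a correlation of 0.044 to 0.392.

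With the sample number as a covariate 84.2%, 37.9%, 25%, 90.8% and 47.4% of calls were kept. For the calls of the inhibitor without nocodazole the median absolute log2 change went from 0.41 to 0.37 and its SE from 0.096 to 0.102, and for the interaction calls the change went from 0.71 to 0.65 and its SE from 0.157 to 0.176. The replicate number as a block kept 95%, 89.5%, 31.2%, 95.1% and 90.3%. Of 24 pairs of libraries with the same replicate number 8 correlated above 0.1 (-0.40 to 0.23), and 3 of 16 libraries correlated best with their own number. Depth of 30987962 to 43321421 counts was not varied, so what it limits was not tested. At the depth and spread simulated, 0% of interactions of 0.3 were recovered.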

Other observations

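Genes of the interferon response moved both ways after nocodazole without inhibitor: 5 of 15 rose and 6 fell (5 and 6 adjusted over the list alone), the median of 0.16 and mean of -0.17 differed in sign, and the list was not called (camera adjusted p = 0.836). Stat2, a transcription factor of that response, was at 154 CPM in DMSO, 93.1 with nocodazole, 175 with inhibitor and 225 with inhibitor plus nocodazole, and its interaction was 1.09 (edgeR adjusted p = 0.000573). Ifit3b, an interferon-induced gene, had a log2 change of -1.95 with nocodazole (edgeR adjusted p = 1.22e-06) and an interaction of 1.88 (edgeR adjusted p = 0.000171). Of 31 proliferation and mitosis genes, 7 rose and 1 fell after nocodazole (6 and 1 adjusted over the list alone, median 0.11, camera adjusted p = 0.333). Bub1b, a spindle checkpoint gene, went from 0.391 to 1.86 CPM, a log2 change of 2.24 (edgeR adjusted p = 2.48e-05), and Mki67 was not called in any comparison.

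Markers of other cell types were measured in the same libraries. Macrophage markers fell in 2 of 5 cases with inhibitor in the presence of nocodazole (3 adjusted over the list alone, median -0.58, camera adjusted p = 0.157). The genes were Cd68 and Aif1. The Aif1 call was lost without nocodazole replicate 2 (edgeR adjusted p = 0.114) or 3 (0.0866), or inhibitor plus nocodazole replicate 3 (0.0917) or 4 (0.118). The Cd68 call was lost without inhibitor plus nocodazole replicate 4 (edgeR adjusted p = 0.0542). After nocodazole without inhibitor, Schwann cell and satellite glia markers rose in 4 of 17 cases and fell in 4 (4 and 4 adjusted over the list alone, median 0.01, mean 0.36, camera adjusted p = 0.898). Their score was 0.16 to 0.50 in the nocodazole libraries and -0.03 to 0.06 in the DMSO libraries, and Ednrb, an endothelin receptor gene, went from 0.248 to 3.57 CPM (edgeR adjusted p = 0.00221). Fibroblast markers rose in 2 and fell in 2 of 15 cases (2 and 2 adjusted over the list alone, median 0.34, camera adjusted p = 0.775), with Dcn at 1.62 (edgeR adjusted p = 0.00665). Macrophage markers rose in 1 of 5 cases (1 adjusted over the list alone, median 0.24, camera adjusted p = 0.456, fry adjusted p = 0.00237), the gene being Cd68, which went from 0.428 to 2.16 CPM (edgeR adjusted p = 0.000486). No endothelial marker (5 measured) and no pericyte or smooth muscle marker (9 measured) was called by edgeR in that comparison, over all genes or adjusted over the list alone (camera adjusted p = 0.84 and 0.592).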
